A study of Mus musculus with 18 samples.

How the data were processed

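Polyadenylated RNA of the left ventricle was sequenced in 18 libraries, 6 for each of 3 groups that the labels' treatment field names: control, isoproterenol, and isoproterenol with minocycline. RNA was extracted with a Qiagen RNeasy lipid tissue kit, per the labels' protocols. Sequencing was paired-end on an Illumina NovaSeq with reads of 150 bases. Per the labels' protocols, reads were trimmed in CLC Genomics Workbench 21.0.3 by its modified-Mott algorithm, with a quality limit of 0.05, at most 2 ambiguous bases and automatic adapter trimming. The same protocols give 784251576 sequences in total and name the RNA-seq module of that program for the transcriptome work. The submitters' processing notes name edgeR without its role. The mapping settings, genome build, gene annotation and treatment of strand are not given in the sources used here.

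The deposited table holds counts per gene and library, titled total counts in its header, for 48709 genes. Only these counts as deposited by the authors were used. The authors' own comparison columns and normalised values were left out. Each column was matched to its library by the number in the description field. The number of per-sample columns that matched no library was 0. Of the gene identifiers, 48349 are in GENCODE release M21 on GRCm38, 48329 of them at overlapping positions and 42754 (88.4%) with identical start and end. Coordinates in the text are those of the deposited table. Where symbols were shared by several identifiers, a suffix kept them apart (238 names).

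Titles give every library a number of its own, while the protocol text speaks of pooled RNA. Whether each library comes from 1 animal is therefore uncertain, and the p-values measure the spread between libraries. No pair of libraries of a group held the same values: chi-square per degree of freedom over genes lay between 5.58 and 35.4 in each such pair. No sequencing batch or date is given in the labels. The library numbers are not shared between groups, so there was no block to fit.

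Genes were kept with edgeR's filterByExpr by group, which left 13281 genes holding 99.93 to 99.95% of the counts of each library. Counts were tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit with robust estimation, glmQLFTest) in a single fit of the 18 libraries with 1 mean per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, over all genes tested in a comparison. The biological coefficient of variation was 13.2% and the median prior degrees of freedom 6.22. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. That of a median over genes comes from a bootstrap over those genes. CPM values use library sizes scaled by TMM, and log2-CPM values carry a prior count of 2. Totals per library did not differ past the threshold between groups in 2-sided exact permutation tests (p = 0.0779, 0.102 and 0.665 for isoproterenol versus control, added minocycline and both drugs versus control). Genes of the mitochondrial genome took a large share of the counts, led by mt-Co1 with 14.6% on average, so counts without the 13 tested ones were an alternative.

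The text names, for each comparison, the 10 called genes with the largest rise and the 10 with the largest fall. These were taken among genes of at least 1 CPM on average over the 12 libraries compared, with a symbol that is no clone or predicted name. From each list it takes examples among up to 4 called members with the smallest p. Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Adrb1, Col1a1, Col3a1, Postn, Timp1, Mmp2, Mmp9, Il6, Il1b, Tnf and Ccl2 were to be reported in any case, some of them by CPM or counts only. Where a comparison called under 10 genes, the 10 with the smallest p were open to mention. Genes are reported as uncertain where another gene of the annotation overlaps them and holds at least 20% as many counts.

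For 37 gene lists, 1115 symbols were written down and 1094 matched the table. The 35 lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), directionally, with adjustment over the lists of a comparison. Alternatives were camera with an estimated correlation, fry, and an exact 2-sided permutation test of the mean log2-CPM of a list per library. Members past the threshold are also counted after adjustment over the list alone. Some lists share genes, such as the matrix and fibroblast lists, so they are not independent.

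Alternatives for the counts of called genes were DESeq2 1.42.0, RLE or upper-quartile scaling, no filter, a filter of 1 CPM in 6 libraries, a fit of the 12 libraries compared, limma-voom with quality weights and a fold change of at least 1.5. Leaving out the mitochondrially encoded genes or each library in turn were further ones. After the values of Myl7 were seen, a fit without the 4 libraries above 80 CPM of Myl7 and a fit with the mean of 3 atrial markers as a covariate were added. "Over 10 alternatives" in the text counts these settings other than the single libraries left out, save the fold threshold. To compare both responses to isoproterenol, genes at an unadjusted p under 0.001 in 3 isoproterenol and 3 control libraries were measured in the libraries not used for the choice, over 40 random divisions.

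The procedures were tested on simulated counts drawn from the real means and library sizes. With 50 genes changed per fold size, the test recovered 20% of 1.25-fold, 62% of 1.5-fold, 88% of 2-fold and 96% of 4-fold changes in the simulation of isoproterenol versus control, with 3 false calls among 13198 genes. For added minocycline it recovered 36%, 66%, 84% and 98% with 8 false calls among 13194 genes. For both drugs versus control it recovered 20%, 60%, 92% and 100% with 4 false calls among 13186 genes. These shares hold for that many changed genes and may be too high where fewer genes change. In a separate simulation, with each gene drawn independently of the others, camera called the shifted list of isoproterenol versus control (adjusted p = 2.37e-19) and of both drugs versus control (adjusted p = 4.31e-27). It called 0 of 36 unchanged lists, but false calls among lists of correlated genes were not tested. No shift was set between the isoproterenol groups, where the shifted list was not called (adjusted p = 0.805 by camera, adjusted p = 0.752 by permutation). The recovery of a shifted list was therefore not tested for added minocycline. The exact permutation test of list means did not call the shifted list in either comparison with control (adjusted p = 0.0801 for each) and called 0 of 36 unchanged ones. That value is the lowest that 924 regroupings allow with a single shifted list among those adjusted, so the test could not have called it. The simulated response ratios of 1 and 0.5 were estimated as 0.994 and 0.496 over 13281 genes.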

Results

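Left ventricles of 12-week-old male C57BL/6J mice were profiled by sequencing of polyadenylated RNA in 3 groups of 6 libraries. Isoproterenol, a synthetic catecholamine that activates β-adrenergic receptors, was infused from an osmotic pump at 30 mg/kg/day, and control animals received saline. The third group received the same infusion together with daily intraperitoneal injections of 50 mg/kg minocycline, a tetracycline antibiotic with anti-inflammatory actions. Tissue was taken after 21 days, and no group given minocycline alone is among the samples used here. Total counts averaged 20208288 ± 2401161 per control library, 17316827 ± 2642256 per isoproterenol library and 19670392 ± 1793420 per library of isoproterenol and minocycline (SD, n = 6 each). Single libraries held 14203041 to 22688664 counts. Mitochondrially encoded genes held 45.4 ± 1.23%, 43.2 ± 2.14% and 44.6 ± 2.06% of the counts in the same order. These shares did not differ past the threshold in 2-sided exact permutation tests (p = 0.0606 for isoproterenol versus control, p = 0.301 for added minocycline and p = 0.413 for both drugs versus control).

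Expression values are means ± SD in CPM, counts scaled to a common library size (n = 6 libraries a group), and fold changes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Every gene said to have changed lay on the stated side of the other group's mean in 6 of 6 libraries, unless another number is given. The libraries counted are those of the first-named group of a comparison, and values of single libraries can still overlap between groups. Called gene lists lay on the stated side of that mean in 6 of 6 libraries of the first-named group unless stated. Gene lists, fixed before the data were examined, were tested with limma's camera, and an adjusted p given for a list is camera's with its preset correlation. With an estimated correlation, 1 list was called for isoproterenol versus control and 0 in each other comparison (8, 6 and 7 lists at an unadjusted p under 0.05 in the same order), against 20, 4 and 19 lists by fry. The first principal component of the log2-CPM values held 28.1% of the variance and separated the control libraries from each treated group (exact permutation p = 0.00217 for both comparisons, the smallest that 924 regroupings can give). The isoproterenol groups with and without minocycline were not separated along it (exact permutation p = 0.346). Myl7, an atrial myosin light chain chosen for mention after its values were seen, ranged from 12.7 to 134 CPM in control, from 8.44 to 96.3 CPM in isoproterenol and from 10.3 to 206 CPM in isoproterenol and minocycline libraries. The mean of the atrial markers Sln, Myl7 and Myl4 did not separate any pair of groups past the threshold (exact permutation p = 0.485, p = 0.359 and p = 0.764). Control 5, Control 6, Isoproterenol 5 and Isoproterenol and minocycline 2 exceeded 80 CPM of Myl7, and counts without these 4 libraries are given beside each comparison.

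**Figure D1:**
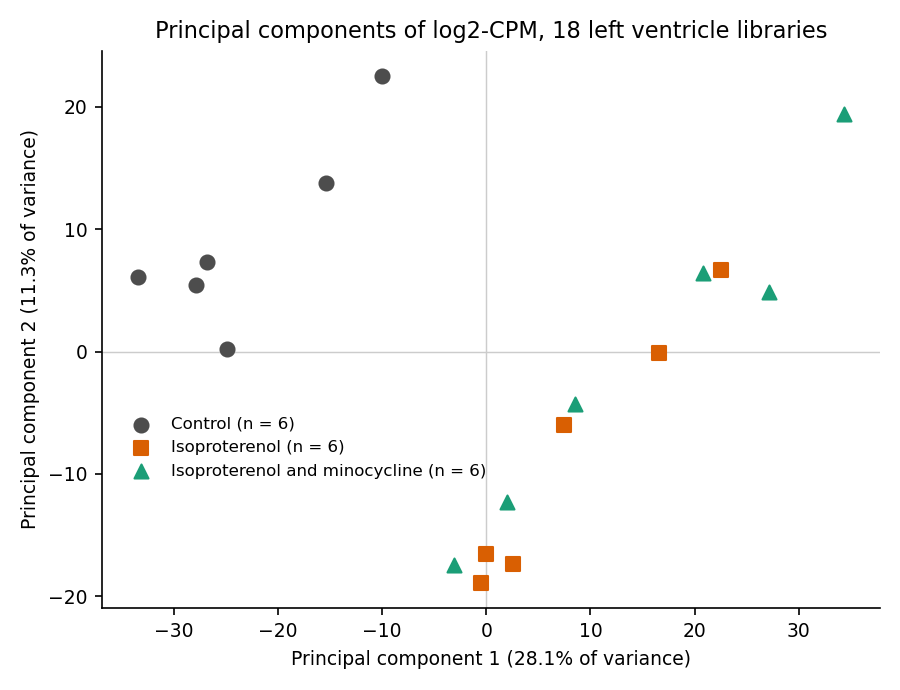
Principal component 1 (28.1% of the variance, horizontal axis) against principal component 2 (11.3%, vertical axis) of log2-CPM values, with 1 point per library coloured by group. The control libraries lie apart from both isoproterenol groups along component 1, and the isoproterenol groups with and without minocycline overlap along it.

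Isoproterenol versus control addressed how the ventricular transcriptome differed after sustained β-adrenergic stimulation. Genes of the extracellular matrix and of macrophages were higher after the infusion. Col3a1, a fibrillar collagen, rose from 98.1 ± 20.2 to 215 ± 46.7 CPM, Timp1, an inhibitor of matrix metalloproteinases, rose 3.25-fold, and Lgals3, which encodes the lectin galectin-3, rose 2.99-fold. Genes of the contractile apparatus and of fatty acid oxidation were lower: Acta1, the skeletal muscle α-actin, fell 4.86-fold and Hadh, a dehydrogenase of mitochondrial β-oxidation, fell 1.60-fold. The natriuretic peptide genes Nppa and Nppb, usual markers of ventricular load, did not pass the test. Of 13281 genes tested, 922 rose and 747 fell, and 150 of the rises and 46 of the falls were at least 2-fold. Without Control 4 there were 580 rises and 499 falls, and without the 4 libraries high in Myl7 there were 372 and 309. With the atrial marker mean as a covariate and all 18 libraries there were 1166 and 895.

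Genes of the sarcomere and Z-disc, which form the contractile lattice, were lower as a group. Of 24 tested members 12 fell, 18 when adjusted over the list alone, and the list was called lower (median log2 fold change -0.23, adjusted p = 2.40e-12, adjusted p = 0.0177 with an estimated correlation). Myom2, an M-band protein, fell from 887 ± 93.2 to 414 ± 60.0 CPM (log2 fold change -1.10, SE 0.11, adjusted p = 7.11e-07). Myoz2, a Z-disc protein that binds calcineurin, fell 1.54-fold, and the ventricular light chains Myl2 and Myl3 fell 1.32-fold and 1.39-fold. Myh6, the α-myosin heavy chain of the adult mouse ventricle, fell 1.28-fold (adjusted p = 4.84e-04).

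The hypertrophy and stress genes went in both directions: 6 of 28 rose and 5 fell, and 7 rose and 6 fell when adjusted over the list alone. The list was not called (adjusted p = 0.940). Fhl1, a LIM-domain protein of the titin complex, rose from 109.8 ± 9.81 to 171 ± 8.70 CPM (log2 fold change 0.64, SE 0.057, adjusted p = 3.65e-07). Sprr1a, a stress-induced small proline-rich protein, rose 15.1-fold from a low level of 0.110 CPM, and Uchl1, a deubiquitinase, rose 1.73-fold. Acta1 (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751) fell from 570.2 ± 348 to 117 ± 39.1 CPM (log2 fold change -2.28, SE 0.45, adjusted p = 0.00380). Myh7 (ENSMUSG00000053093, chromosome 14, 54970688 to 54994634), the β-myosin heavy chain that rodent hearts express before birth, fell from 210.4 ± 137 to 70.7 ± 44.5 CPM (log2 fold change -1.58, SE 0.47, adjusted p = 0.0391). Its annotation overlaps the long noncoding RNA Mhrt, so its counts may hold reads of that gene. The Myh7 call was lost without Control 2, 3 or 6 or Isoproterenol 1, 2, 3, 4 or 6 (adjusted p = 0.0510 to 0.0926), without a filter on low counts and in a fit of the 12 libraries alone (adjusted p = 0.00993 to 0.0712 over 10 alternatives). Nppa and Nppb, at 153 ± 58.9 and 150.0 ± 65.5 CPM in control, were at 88.2 ± 44.0 and 91.5 ± 21.8 CPM after isoproterenol, lower in 5 and 6 of 6 libraries but not past the threshold (log2 fold changes -0.80, SE 0.40, adjusted p = 0.208, and -0.71, SE 0.33, adjusted p = 0.169). Nppa passed it with the atrial marker mean as a covariate (adjusted p = 0.0397 to 0.285 over the alternatives).

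**Figure D2:**
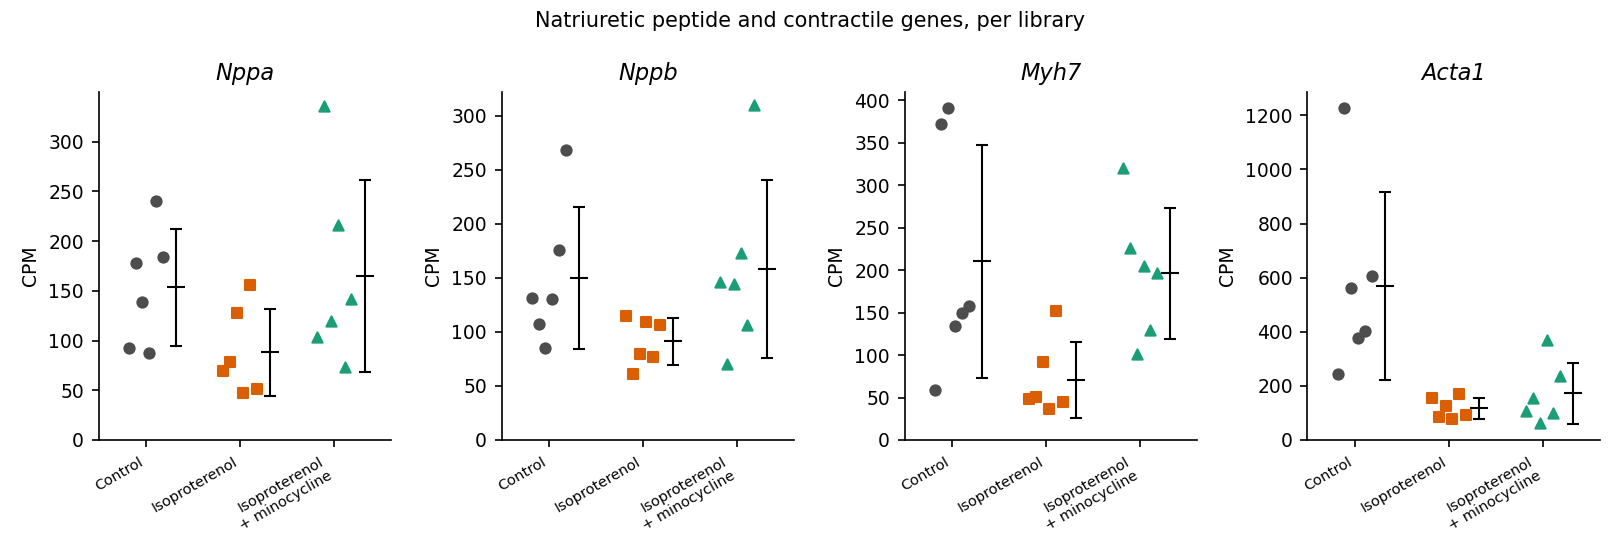
CPM (vertical axis, linear from 0) of Nppa, Nppb, Myh7 and Acta1 in each library of the 3 groups (horizontal axis), with points for libraries and bars for the group mean ± SD (n = 6). Acta1 was 570.2 CPM in control, 117 in isoproterenol and 173 in isoproterenol and minocycline libraries on average, and Myh7 was 210.4, 70.7 and 196.

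Matrix genes rose widely. Of 60 extracellular matrix genes 28 rose, 43 when adjusted over the list alone (median log2 fold change 0.55, adjusted p = 6.85e-17, adjusted p = 0.227 with an estimated correlation). Sfrp2, a secreted Wnt modulator, rose 3.26-fold, Tnc, the matricellular glycoprotein tenascin-C, rose 3.35-fold and Col14a1, a fibril-associated collagen, rose 2.13-fold. Among fibroblast and myofibroblast markers 13 of 30 rose, 19 adjusted over the list alone (adjusted p = 7.69e-09, adjusted p = 0.295 with an estimated correlation), among them Col1a2 from 80.6 ± 11.3 to 130.5 ± 18.6 CPM and Pcolce, an enhancer of procollagen processing, by 1.51-fold. Postn, the matricellular protein periostin, rose 2.49-fold (log2 fold change 1.31, SE 0.30, adjusted p = 0.00902), and Col1a1 rose 1.76-fold. Both calls were lost without the 4 libraries high in Myl7 (adjusted p = 3.43e-04 to 0.116 and 1.40e-04 to 0.0849 over 10 alternatives). Of the matrix proteases and inhibitors 12 of 28 rose and 1 fell, 14 and 1 adjusted over the list alone (adjusted p = 1.23e-05, adjusted p = 0.190 with an estimated correlation). They included Mmp12, a macrophage elastase (5.29-fold from 0.414 CPM), the cathepsins Ctss (1.66-fold) and Ctsk (1.87-fold), and Mmp2, a gelatinase (1.56-fold). Smooth muscle and pericyte markers were called higher with 4 of 17 rising, 4 adjusted over the list alone, such as Higd1b, a pericyte marker, by 1.44-fold (adjusted p = 0.00884, adjusted p = 0.405 with an estimated correlation).

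Markers of macrophages and mast cells were also higher. Of 31 macrophage and monocyte markers 14 rose, 22 adjusted over the list alone (adjusted p = 3.46e-09, adjusted p = 0.227 with an estimated correlation), including Lgals3 from 2.56 ± 0.545 to 7.70 ± 1.57 CPM, Mpeg1, a pore-forming protein of phagocytes (1.79-fold), and Ms4a7 (2.47-fold). Mast cell markers rose in 3 of 6 members, 5 adjusted over the list alone (adjusted p = 0.00131, adjusted p = 0.141 with an estimated correlation). Among them the tryptase Tpsb2 rose 2.31-fold from 0.779 CPM. Complement genes rose in 11 of 19 members, 14 adjusted over the list alone (adjusted p = 2.31e-08, adjusted p = 0.227 with an estimated correlation), with C3, the central complement component, going from 113 ± 14.4 to 197 ± 30.7 CPM. Of the inflammatory cytokine and NF-κB genes 14 of 40 rose and 1 fell, 17 and 1 adjusted over the list alone (adjusted p = 5.25e-07, adjusted p = 0.201 with an estimated correlation). Ccl2 and Ccl12, chemokines that attract monocytes, rose 2.06-fold and 3.44-fold, the latter from 0.597 CPM. Socs3, a feedback inhibitor of cytokine signalling, rose 2.12-fold. Counts of Il6, Il1b, Tnf and Mmp9 were too low to test (46, 143, 94 and 127 over the 18 libraries).

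Interferon-stimulated genes were called higher with 6 of 36 rising, 6 adjusted over the list alone (adjusted p = 7.60e-04, adjusted p = 0.397 with an estimated correlation). Ifi27l2a rose 1.88-fold, and Irf7, an interferon regulatory factor whose annotation overlaps Phrf1, rose 1.61-fold. Antigen presentation genes were called higher in 5 of 6 libraries, although 2 of 22 rose and 1 when adjusted over the list alone (adjusted p = 0.00770, adjusted p = 0.564 with an estimated correlation). Of these, H2-Ab1, an MHC class II chain, rose 1.30-fold in 4 of 6 libraries (adjusted p = 0.0429). That call was lost without any of Control 2 to 6 and Isoproterenol 3 to 6 (adjusted p = 0.0622 to 0.0950), without a filter on low counts and without the 4 libraries high in Myl7 (adjusted p = 0.0302 to 0.256 over 10 alternatives). The 5 tested markers of T, B and NK cells were not called (median log2 fold change 0.091, adjusted p = 0.995). Of 3 tested neutrophil markers, too few for a list test, 2 rose when adjusted over the list alone.

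Genes of mitochondrial energy metabolism were lower. Of 42 fatty acid oxidation genes 24 fell and 1 rose, 25 and 1 adjusted over the list alone (median log2 fold change -0.32, adjusted p = 9.98e-14, adjusted p = 0.201 with an estimated correlation). Hadh fell from 391 ± 36.3 to 244 ± 15.1 CPM (log2 fold change -0.68, SE 0.079, adjusted p = 6.89e-06). Decr1, an auxiliary enzyme of β-oxidation, and Eci1, an enoyl-CoA isomerase, fell 1.45-fold and 1.505-fold, and Fabp3, the heart fatty acid binding protein, fell 1.32-fold. In the TCA cycle and branched-chain amino acid list 13 of 30 fell and 1 rose, 17 and 1 adjusted over the list alone (adjusted p = 1.12e-08, adjusted p = 0.370 with an estimated correlation), including Acat1 (1.32-fold), Suclg1, a subunit of succinyl-CoA ligase (1.21-fold), and Bcat2, a branched-chain aminotransferase (1.26-fold). Nuclear genes of oxidative phosphorylation fell in 18 of 73 members, 25 adjusted over the list alone (adjusted p = 1.58e-09, adjusted p = 0.370 with an estimated correlation), such as 1.25-fold for Cox6a2, the heart and muscle subunit of cytochrome oxidase. Of 13 mitochondrially encoded protein genes 5 fell, 8 adjusted over the list alone, among them mt-Nd4 by 1.20-fold and mt-Co2 by 1.20-fold (adjusted p = 5.00e-06, adjusted p = 0.324 with an estimated correlation).

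Mitochondrial ribosome genes were called lower with a median log2 fold change of -0.085 (adjusted p = 0.00124, adjusted p = 0.564 with an estimated correlation), but 4 of 85 rose and 4 fell, the same counts as adjusted over the list alone. Mrps35 fell 1.25-fold while Mrpl16 rose 1.23-fold, both structural proteins of that ribosome. The mitochondrial and integrated stress response list was not called, with 4 of 32 rising and 2 falling, 5 and 4 adjusted over the list alone (adjusted p = 0.361). Atf5, a transcription factor of the mitochondrial unfolded protein response whose annotation overlaps Nup62, rose 1.51-fold. Glucose use and glycolysis genes were not called either, with 3 of 32 rising and 5 falling, 3 and 7 adjusted over the list alone (adjusted p = 0.235). Within that list Ldha, a lactate dehydrogenase subunit, rose from 424 ± 31.2 to 556 ± 26.3 CPM and Pdk2, a kinase that inhibits pyruvate dehydrogenase, fell 1.25-fold. Cytosolic ribosomal protein genes were called lower in 5 of 6 libraries by a median of -0.11 on the log2 scale, and 10 of 64 fell, 10 adjusted over the list alone (adjusted p = 7.52e-09, adjusted p = 0.397 with an estimated correlation), such as Rps28, whose annotation overlaps Kank3, by 1.24-fold.

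Among genes of β-adrenergic signalling 6 of 38 rose and 3 fell, 10 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.167). Grk5, a kinase that desensitises β-adrenergic receptors, rose from 18.1 ± 2.43 to 36.9 ± 3.82 CPM (log2 fold change 1.03, SE 0.096, adjusted p = 3.85e-07), with the limit that its annotation overlaps Zfp950. Gnai2, an inhibitory G protein subunit, rose 1.28-fold and Adcy6, an adenylyl cyclase of cardiomyocytes, fell 1.27-fold. Adrb1, the β1-adrenergic receptor, did not pass the test (log2 fold change -0.26, SE 0.18, adjusted p = 0.376, lower in 5 of 6 libraries). Calcium handling and ion channel genes were called lower in 5 of 6 libraries, with 7 of 40 falling and 1 rising, 7 and 2 adjusted over the list alone (adjusted p = 0.0222, adjusted p = 0.564 with an estimated correlation). S100a1, a calcium-binding regulator of contractility, fell 1.25-fold and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell 1.35-fold. Atp2a2, the sarcoplasmic reticulum calcium pump, was at 8138 ± 647 and 8292 ± 862 CPM (log2 fold change 0.027, SE 0.14, adjusted p = 0.925).

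Cell cycle genes were called higher, with 7 of 35 rising, 8 adjusted over the list alone, and a median log2 fold change of 0.54 (adjusted p = 7.62e-07, adjusted p = 0.141 with an estimated correlation). Cdk1, the mitotic kinase, rose 2.42-fold from 0.526 CPM. Antioxidant and NRF2 genes rose in 8 of 30 members, 11 adjusted over the list alone, where 3 also fell (adjusted p = 0.00298, adjusted p = 0.0811 with an estimated correlation). Among them were Gpx1 and Gpx3, glutathione peroxidases (1.39-fold and 1.63-fold), and Hmox1, heme oxygenase (1.80-fold). Cell death and autophagy genes rose in 6 of 32 members, 6 adjusted over the list alone (adjusted p = 0.00884, adjusted p = 0.0811 with an estimated correlation), such as Bnip3 by 1.37-fold and Bax by 1.25-fold. Immediate early genes were called higher (adjusted p = 0.0366, adjusted p = 0.641 with an estimated correlation), with 2 called members of 23, 2 adjusted over the list alone. They were Junb, whose annotation overlaps Prdx2 (1.77-fold), and Nr4a3, an orphan nuclear receptor (3.81-fold), a call lost without the 4 libraries high in Myl7 (adjusted p = 0.00148 to 0.129 over 10 alternatives).

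The remaining lists were not called. They were the renin-angiotensin and vasoactive peptide genes (adjusted p = 0.166) and the endothelial markers (adjusted p = 0.5005), in which Aqp1, a water channel, fell 1.67-fold. The lymphatic endothelial markers (adjusted p = 0.774) included Pdpn, which rose 1.91-fold. The circadian clock genes were not called either (adjusted p = 0.809). Atrial and conduction markers (adjusted p = 0.988), adipocyte markers (adjusted p = 0.455), erythroid markers (adjusted p = 0.166) and mesothelial and Schwann markers (adjusted p = 0.988) completed them. Their medians were -0.18, 0.26, -0.49 and 0.065 on the log2 scale. For the T, B and NK cell, adipocyte and mesothelial lists camera's direction was lower although median and mean were above 0, and the lymphatic median lay below 0 with a mean above it. Only 2 skeletal muscle markers could be tested, with a median of -0.40.

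The 10 largest rises among genes of at least 1 CPM on average over the 12 libraries compared were Snhg11 (16.1-fold), Lrrc10b (11.1-fold), AI593442, Mmp12, Enkur, Cdo1, Krt18, Olfml2b, Nr4a3 and Clec4n (3.53-fold). Snhg11 (ENSMUSG00000044349, chromosome 2, 158375638 to 158386145), a small nucleolar RNA host gene, went from 0.851 ± 0.154 to 13.8 ± 5.78 CPM (log2 fold change 4.01, SE 0.32, adjusted p = 3.65e-07), and Cdo1, the cysteine dioxygenase of taurine synthesis, from 2.90 ± 0.892 to 12.6 ± 2.92 CPM. Of these rises, Lrrc10b, AI593442, Mmp12, Enkur and Krt18 also started from low control means (0.292, 0.497, 0.414, 0.588 and 0.519 CPM). The 10 largest falls were Cngb3 (6.86-fold), Acta1, Edn3, Snai3, Scgb1c1, Fgf6, Gnb3, Ramp1, Nrgn and Myh7 (2.98-fold). Gnb3, a G protein β subunit, fell from 10.8 ± 1.32 to 3.14 ± 0.613 CPM, Ramp1, a co-receptor for calcitonin-family peptides, fell 3.22-fold, and the endothelin gene Edn3 fell 4.36-fold. Snai3 overlaps Gm20388 in the annotation. Without the 4 libraries high in Myl7, Fgf6 and Nrgn no longer passed (adjusted p = 3.69e-04 to 0.156 and 0.00502 to 0.0512 over 10 alternatives), and Nrgn did not pass without Control 5 (adjusted p = 0.0504).

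Isoproterenol and minocycline versus isoproterenol addressed what minocycline added to the infusion, and few single genes passed the test: 1 rose and 6 fell, against 515 higher and 495 lower at an unadjusted p under 0.05. Ptgds (ENSMUSG00000015090, chromosome 2, 25466709 to 25470046), the lipocalin-type prostaglandin D synthase, rose 2.58-fold from 165 ± 26.2 to 427 ± 81.4 CPM (log2 fold change 1.37, SE 0.14, adjusted p = 1.81e-04) and stood at 339 ± 66.4 CPM in control. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287827) and H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34263209 to 34269418), the chains of an MHC class II molecule that presents antigen to helper T cells, fell 1.67-fold and 1.64-fold. H2-Aa went from 36.3 ± 8.02 to 21.7 ± 3.04 CPM, against 29.7 ± 3.03 in control. Its values overlapped between isoproterenol and added-minocycline libraries (23.8 to 45.9 and 18.6 to 25.6 CPM). So did those of H2-Ab1 (18.9 to 32.8 and 13.6 to 19.5 CPM). The other falls were Prnd (ENSMUSG00000027338, chromosome 2, 131950861 to 131956130), which encodes the prion-like protein doppel (4.02-fold, adjusted p = 0.0333), Camk2b (ENSMUSG00000057897, chromosome 11, 5969644 to 6066362), a calmodulin-dependent kinase subunit (1.39-fold, adjusted p = 0.0333), and the clone-named genes 2210407C18Rik (ENSMUSG00000037145, chromosome 11, 58608204 to 58616075, 2.52-fold) and 3425401B19Rik (ENSMUSG00000071540, chromosome 14, 32659119 to 32685272, 1.35-fold).

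The Ptgds call held under each of 10 alternatives (adjusted p = 3.50e-18 to 0.00685) and without each of the 18 libraries. The H2-Aa and H2-Ab1 calls were each lost without Isoproterenol 3, 4, 5 or 6 or Isoproterenol and minocycline 1, 3, 4 or 5 (adjusted p = 0.0628 to 0.101 and 0.0582 to 0.101), in a fit of the 12 libraries and without the 4 libraries high in Myl7 (adjusted p = 1.03e-04 to 0.250 and 1.03e-04 to 0.250 over the alternatives). Prnd was lost without Control 3, 5 or 6, Isoproterenol 1, 3, 4, 5 or 6 or Isoproterenol and minocycline 1 to 5 (adjusted p = 0.0534 to 0.119). Camk2b was lost without 8 single libraries (Isoproterenol 3 to 6, Isoproterenol and minocycline 1, 2, 4 and 5, adjusted p = 0.0597 to 0.113). Over the alternatives the adjusted p of Prnd was 4.09e-05 to 0.302 and that of Camk2b 0.00284 to 0.302. Of the clone-named genes, 3425401B19Rik was lost without Isoproterenol 6 or Isoproterenol and minocycline 1 or 4 (adjusted p = 0.0521 to 0.0971), and 2210407C18Rik also without Isoproterenol and minocycline 5 (adjusted p = 0.0521 to 0.0971). Over the alternatives their adjusted p was 2.57e-05 to 0.133 and 2.57e-05 to 0.133. The next genes by p were Apln, the peptide apelin, H2-Eb1, another MHC class II chain, and Gnmt, a methyltransferase, with log2 fold changes of -0.76, -0.69 and 1.04 in 6 of 6 libraries, SE 0.15, 0.13 and 0.21 (adjusted p = 0.0671 for each). DESeq2 called all 3 (adjusted p = 0.00195 to 0.231, 0.00155 to 0.400 and 0.00195 to 0.376 over the alternatives) and counted 14 rises and 21 falls. The count of falls was 0 without Isoproterenol 6 or Isoproterenol and minocycline 1 or 4 (367, 418 and 399 at an unadjusted p under 0.05), 1 without Isoproterenol and minocycline 5, 2 without Isoproterenol 3 or 4, 3 without Isoproterenol 5, 9 without Isoproterenol 2, 11 without Isoproterenol and minocycline 6 and 0 without the 4 libraries high in Myl7 (450 at an unadjusted p under 0.05). The count of rises was 2 without Isoproterenol 2 or Isoproterenol and minocycline 3 or 6.

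**Figure D3:**
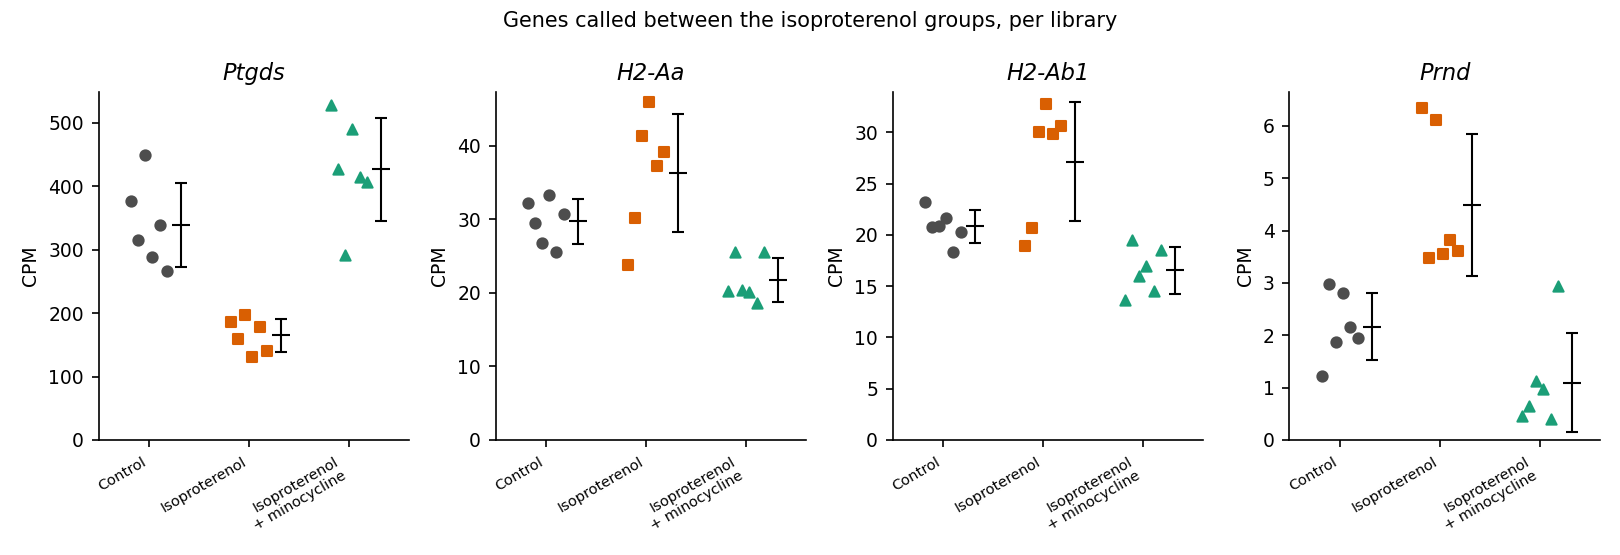
CPM (vertical axis, linear from 0) of Ptgds, H2-Aa, H2-Ab1 and Prnd in each library of the 3 groups (horizontal axis), with points for libraries and bars for the group mean ± SD (n = 6). Ptgds averaged 339 CPM in control, 165 in isoproterenol and 427 in isoproterenol and minocycline libraries.

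Among the fixed lists, cell cycle genes were lower with added minocycline, by a median of -0.46 on the log2 scale, and 6 of 35 fell when adjusted over the list alone (adjusted p = 4.86e-11, adjusted p = 0.0556 with an estimated correlation). Of 28 markers of T, B and NK cells 5 were tested, 3 of them immunoglobulin genes of B cells and none an NK cell marker. They were lower by a median of -0.45, with 4 of 5 falling when adjusted over the list alone (adjusted p = 4.26e-05, adjusted p = 0.0556 with an estimated correlation). An exact permutation test of the list mean per library also called them (adjusted p = 0.0379). Cell death and autophagy genes were lower by a median of -0.051 (adjusted p = 0.0112, adjusted p = 0.0556 with an estimated correlation), and the exact permutation test called them as well (adjusted p = 0.0379). For both lists the unadjusted permutation p was 0.00217, the smallest that 924 regroupings can give. Antigen presentation genes were called lower in 4 of 6 libraries, with H2-Aa and H2-Ab1 as the called members (2 of 22 fell, 4 adjusted over the list alone, median -0.17, adjusted p = 1.61e-05, adjusted p = 0.517 with an estimated correlation). Cytosolic ribosomal protein genes were higher by a median of 0.15, and 43 of 64 rose when adjusted over the list alone (adjusted p = 7.74e-34, adjusted p = 0.120 with an estimated correlation). Hypertrophy and stress genes were higher by a median of 0.33 (adjusted p = 7.61e-05, adjusted p = 0.260 with an estimated correlation), with 8 of 28 higher at an unadjusted p under 0.05. The exact permutation test did not call the cell cycle, antigen presentation, ribosomal protein and hypertrophy lists (adjusted p = 0.101, 0.549, 0.133 and 0.189). The medians of these lists and of the T, B and NK cell and cell death lists have the opposite sign in isoproterenol versus control, and since both comparisons use the same isoproterenol libraries they share the chance values of that group.

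Camera called 10 other lists, none of which the exact permutation test called (adjusted p = 0.189 to 0.864). The medians of the sarcomere, lymphatic and erythroid lists also have the opposite sign in isoproterenol versus control. Higher were the sarcomere list (median 0.074, 5 of 6 libraries, adjusted p = 0.0143, adjusted p = 0.504 with an estimated correlation) and fibroblast markers (median 0.14, 3 of 6, adjusted p = 0.0245, adjusted p = 0.767 with an estimated correlation). So were complement genes (median 0.077, 4 of 6, adjusted p = 0.0392, adjusted p = 0.767 with an estimated correlation). Lymphatic endothelial markers were higher (median 0.13, adjusted p = 0.00470, adjusted p = 0.247 with an estimated correlation, 3 of 7 rising when adjusted over the list alone), as were immediate early genes (median 0.17, 4 of 6, adjusted p = 0.0168, adjusted p = 0.767 with an estimated correlation). Markers of tissue that can be taken along with the ventricle were higher too. Adipocyte markers had a median of 0.83 (5 of 6, adjusted p = 0.00319, adjusted p = 0.544 with an estimated correlation). The median was 0.46 for mesothelial and Schwann markers (5 of 6, adjusted p = 0.00180, adjusted p = 0.472 with an estimated correlation) and 0.67 for erythroid markers (4 of 6, adjusted p = 0.0107, adjusted p = 0.708 with an estimated correlation). Lower were the calcium handling list (median -0.078, 3 of 6, adjusted p = 0.00319, adjusted p = 0.708 with an estimated correlation) and the TCA cycle list (median -0.084, 4 of 6, adjusted p = 0.00464, adjusted p = 0.767 with an estimated correlation). Isoproterenol and minocycline 4 and 6 had the lowest mean log2-CPM of both lists (5.524 and 5.597 for calcium handling, 7.396 and 7.525 for the TCA cycle). The others of that group had 5.807 to 5.98 and 7.649 to 7.913. Isoproterenol libraries had 5.865 to 6.023 and 7.668 to 7.874. With the atrial marker mean as a covariate the calls of the fibroblast, complement, immediate early and TCA cycle lists ended (adjusted p = 0.442, 0.442, 0.0529 and 0.146).

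The other 19 tested lists were not called, with medians between -0.063 and 0.28 on the log2 scale. Extracellular matrix genes had a median of 0.039 (adjusted p = 0.985), macrophage markers of 0.045 (adjusted p = 0.538), inflammatory genes of 0.067 (adjusted p = 0.112) and fatty acid oxidation genes of -0.040 (adjusted p = 0.0757). The median and mean of the mast cell, antioxidant and renin-angiotensin lists differed in sign, and for glycolysis both lay below 0 while camera's direction was higher. Col3a1, Col1a1, Postn and Timp1 did not differ past the threshold between these groups (log2 fold changes -0.34, -0.11, 0.0070 and 0.48, adjusted p = 0.718, 0.895, 0.997 and 0.706). Neither did Ccl2 (0.27, adjusted p = 0.761), Nppa (0.91, adjusted p = 0.615), Nppb (0.79, adjusted p = 0.593), Myh7 (1.48, adjusted p = 0.469) or Acta1 (0.56, adjusted p = 0.774). Myh6, Adrb1, Mmp2 and Atp2a2 were not called either. They averaged 23340, 4.889, 71.26 and 8292 CPM in isoproterenol libraries and 24920, 3.931, 66.8 and 7676 CPM with added minocycline. Atp2a2 was at 4846 and 5524 CPM in Isoproterenol and minocycline 4 and 6, and at 8272 to 9708 CPM in the others of that group. The intervals of such differences were wide: the SE of the Myh7 change was 0.47 and that of the Nppa change 0.40 on the log2 scale.

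Isoproterenol and minocycline versus control showed how hearts given both drugs differed from control hearts, with 1355 genes rising and 1202 falling. Matrix, fibroblast and macrophage genes were again higher and sarcomere and fatty acid oxidation genes lower. Col3a1 was at 169.6 ± 59.1 CPM (1.73-fold higher than control), Timp1 rose 4.53-fold and Lgals3 rose 3.19-fold, while Hadh fell 1.78-fold and Acta1 fell 3.30-fold. Serpina3n, an acute-phase protease inhibitor, rose from 14.7 ± 7.16 to 84.3 ± 37.8 CPM (log2 fold change 2.51, SE 0.34, adjusted p = 1.18e-04). Of the rises 201 and of the falls 53 were at least 2-fold. Without the 4 libraries high in Myl7 the counts were 756 and 613 (1369 and 1225 with the atrial marker mean as a covariate), and Col3a1, Col1a1, Postn and Acta1 no longer passed (adjusted p = 0.00444 to 0.0919, 0.00109 to 0.0815, 2.31e-04 to 0.0733 and 3.36e-04 to 0.0623 over 10 alternatives).

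Of 60 matrix genes 36 rose and 1 fell, 43 and 1 adjusted over the list alone (adjusted p = 1.62e-14, adjusted p = 0.293 with an estimated correlation), and 22 of 30 fibroblast markers rose, 25 adjusted over the list alone (adjusted p = 1.21e-10, adjusted p = 0.292 with an estimated correlation). Tnc rose 3.58-fold, Sfrp2 2.73-fold and Mfap5, a microfibril protein, 2.20-fold. Matrix proteases and inhibitors rose in 15 of 28 members, 15 adjusted over the list alone, where 1 fell (adjusted p = 3.36e-06, adjusted p = 0.238 with an estimated correlation), including Mmp12 (6.38-fold) and the stromelysin Mmp3 (2.38-fold). Smooth muscle and pericyte markers rose in 5 of 17 members, 7 adjusted over the list alone (adjusted p = 0.00155, adjusted p = 0.342 with an estimated correlation), with Acta2, the smooth muscle α-actin, going from 68.4 ± 14.6 to 121 ± 25.5 CPM. Lymphatic endothelial markers rose in 2 of 7 members, 3 adjusted over the list alone (adjusted p = 0.0404, adjusted p = 0.328 with an estimated correlation), with Pdpn at 2.06-fold its control level. Endothelial markers were not called as a list (adjusted p = 0.0855), although 5 of 19 rose and 1 fell, 6 and 1 adjusted over the list alone. Pecam1, an endothelial adhesion molecule, rose 1.31-fold and Aqp1 fell 1.97-fold.

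Macrophage markers rose in 19 of 31 members, 23 adjusted over the list alone, where 1 fell (adjusted p = 4.56e-09, adjusted p = 0.292 with an estimated correlation), with Mrc1, the mannose receptor of resident macrophages, going from 18.8 ± 2.37 to 34.1 ± 3.38 CPM. Complement genes rose in 14 of 19 members, 17 adjusted over the list alone (adjusted p = 2.41e-09, adjusted p = 0.238 with an estimated correlation), including C3 (2.11-fold) and the complement inhibitor Serping1 (1.80-fold). Of the inflammatory genes 16 of 40 rose and 2 fell, 19 and 2 adjusted over the list alone (adjusted p = 9.08e-08, adjusted p = 0.238 with an estimated correlation), with Ccl2 rising 2.50-fold and Osmr, the oncostatin M receptor, 1.66-fold. Mast cell markers rose in 4 and fell in 1 of 6 members, the same counts as adjusted over the list alone (adjusted p = 0.0126, adjusted p = 0.238 with an estimated correlation). The chymase Cma1 rose 2.65-fold from 0.629 CPM. Interferon-stimulated genes were called higher in 5 of 6 libraries, with 8 of 36 rising and 2 falling, the same counts as adjusted over the list alone (adjusted p = 0.0382, adjusted p = 0.589 with an estimated correlation). Ifi27l2a rose 2.59-fold and Iigp1, an interferon-inducible GTPase, fell 1.48-fold. T, B and NK cell markers were called lower, with 2 of 5 falling, 3 adjusted over the list alone (adjusted p = 0.0242, adjusted p = 0.292 with an estimated correlation), such as the immunoglobulin heavy chain gene Ighm (1.91-fold). Antigen presentation genes were not called (adjusted p = 0.716), while H2-Aa fell 1.36-fold (adjusted p = 0.0190).

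Fatty acid oxidation genes fell in 28 and rose in 1 of 42 members, 29 and 2 adjusted over the list alone (adjusted p = 2.28e-13, adjusted p = 0.238 with an estimated correlation). TCA cycle and branched-chain amino acid genes fell in 18 and rose in 1 of 30, 22 and 1 adjusted over the list alone (adjusted p = 7.01e-11, adjusted p = 0.323 with an estimated correlation). Decr1 fell 1.58-fold, Fabp3 1.43-fold and Bckdha, a subunit of the branched-chain ketoacid dehydrogenase, 1.36-fold. Nuclear oxidative phosphorylation genes fell in 19 and rose in 1 of 73 members, 21 and 1 adjusted over the list alone (adjusted p = 2.57e-06, adjusted p = 0.528 with an estimated correlation), for example Ndufa3 by 1.32-fold. Mitochondrially encoded genes fell in 5 of 13, 5 adjusted over the list alone, and were called in 5 of 6 libraries (adjusted p = 0.00245, adjusted p = 0.528 with an estimated correlation). Mitochondrial ribosome genes were called lower, with 11 of 85 falling and 4 rising, the same counts as adjusted over the list alone (adjusted p = 0.00880, adjusted p = 0.589 with an estimated correlation). The stress response list was not called (adjusted p = 0.549), but Hspd1, the mitochondrial chaperonin whose annotation overlaps Hspe1, fell 1.55-fold. Glycolysis genes were not called (adjusted p = 0.350), and Hk1, a hexokinase, rose 1.35-fold.

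Sarcomere genes fell in 13 of 24 members, 15 adjusted over the list alone (adjusted p = 8.99e-08, adjusted p = 0.144 with an estimated correlation), with Myom2 at 499.5 ± 73.3 CPM (1.78-fold lower than control) and Mylk4, a myosin light chain kinase family member, falling 3.57-fold. Calcium handling genes fell in 11 and rose in 2 of 40, 12 and 2 adjusted over the list alone (adjusted p = 1.64e-04, adjusted p = 0.386 with an estimated correlation), among them the pacemaker channel Hcn2 (1.69-fold). The hypertrophy and stress list was not called (adjusted p = 0.0855), with 8 of 28 rising and 4 falling, 8 and 5 adjusted over the list alone. Nppa, Nppb and Myh7 lay near control (log2 fold changes 0.11, 0.078 and -0.100, SE 0.39, 0.32 and 0.46, adjusted p = 0.880, 0.892 and 0.902). Myh6, Atp2a2 and Mmp2 averaged 24920, 7676 and 66.8 CPM with both drugs, against 29930, 8138 and 45.56 CPM in control. β-Adrenergic signalling genes were not called (adjusted p = 0.601). Grk5 rose 2.00-fold, and Adrb1 fell 1.48-fold (adjusted p = 0.0346), a call lost without Control 4, 5 or 6 or Isoproterenol and minocycline 4 or 6 (adjusted p = 0.0557 to 0.0801) and under alternatives (adjusted p = 0.0189 to 0.0689). Antioxidant genes rose in 10 and fell in 3 of 30 members, 11 and 6 adjusted over the list alone (adjusted p = 0.0201, adjusted p = 0.238 with an estimated correlation), including Gpx1 (1.57-fold). Immediate early genes rose in 4 of 23, 4 adjusted over the list alone (adjusted p = 0.00143, adjusted p = 0.528 with an estimated correlation), including Fos (2.91-fold) and Junb (2.34-fold).

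Cell cycle genes, called in both other comparisons, were not called here, with 2 of 35 rising and a median of -0.0071 beside a mean above 0 (adjusted p = 0.571). Lists that were not called also included cytosolic ribosomal protein genes (median 0.041, adjusted p = 0.106), renin-angiotensin genes (adjusted p = 0.424), cell death genes (adjusted p = 0.414) and circadian clock genes (adjusted p = 0.920). In the renin-angiotensin list Edn1, the vasoconstrictor endothelin-1, rose 2.51-fold, and Apln fell 1.51-fold. The same held for the atrial (adjusted p = 0.571), adipocyte (median 1.22, adjusted p = 0.350), erythroid (adjusted p = 0.820) and mesothelial markers (adjusted p = 0.0730). The 10 largest rises were Snhg11 (20.5-fold), Lrrc10b, Clec4d, Mmp12, Serpina3n, Krt18, AI593442, Pck1, Cdo1 and Enkur (4.64-fold), and the 10 largest falls were Cngb3 (9.32-fold), Fgf6, Snai3, Scgb1c1, Edn3, Gnb3, Cyp1a1, Mylk4, Acta1 and Tmem82 (2.73-fold). Clec4d, a C-type lectin of myeloid cells, rose 8.29-fold from a low level of 0.258 CPM. Pck1, an enzyme of gluconeogenesis that is also a member of the adipocyte list (median 1.22), was above the control mean in 5 of 6 libraries. Its call was lost without Control 1, 3, 4 or 6 or Isoproterenol and minocycline 2 or 4 (adjusted p = 0.0517 to 0.104, and 0.00885 to 0.186 over 10 alternatives), that of Cyp1a1 without Control 3 (adjusted p = 0.0510), and that of Fgf6 without the 4 libraries high in Myl7 (adjusted p = 3.73e-05 to 0.0524 over the alternatives).

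**Figure D4:**
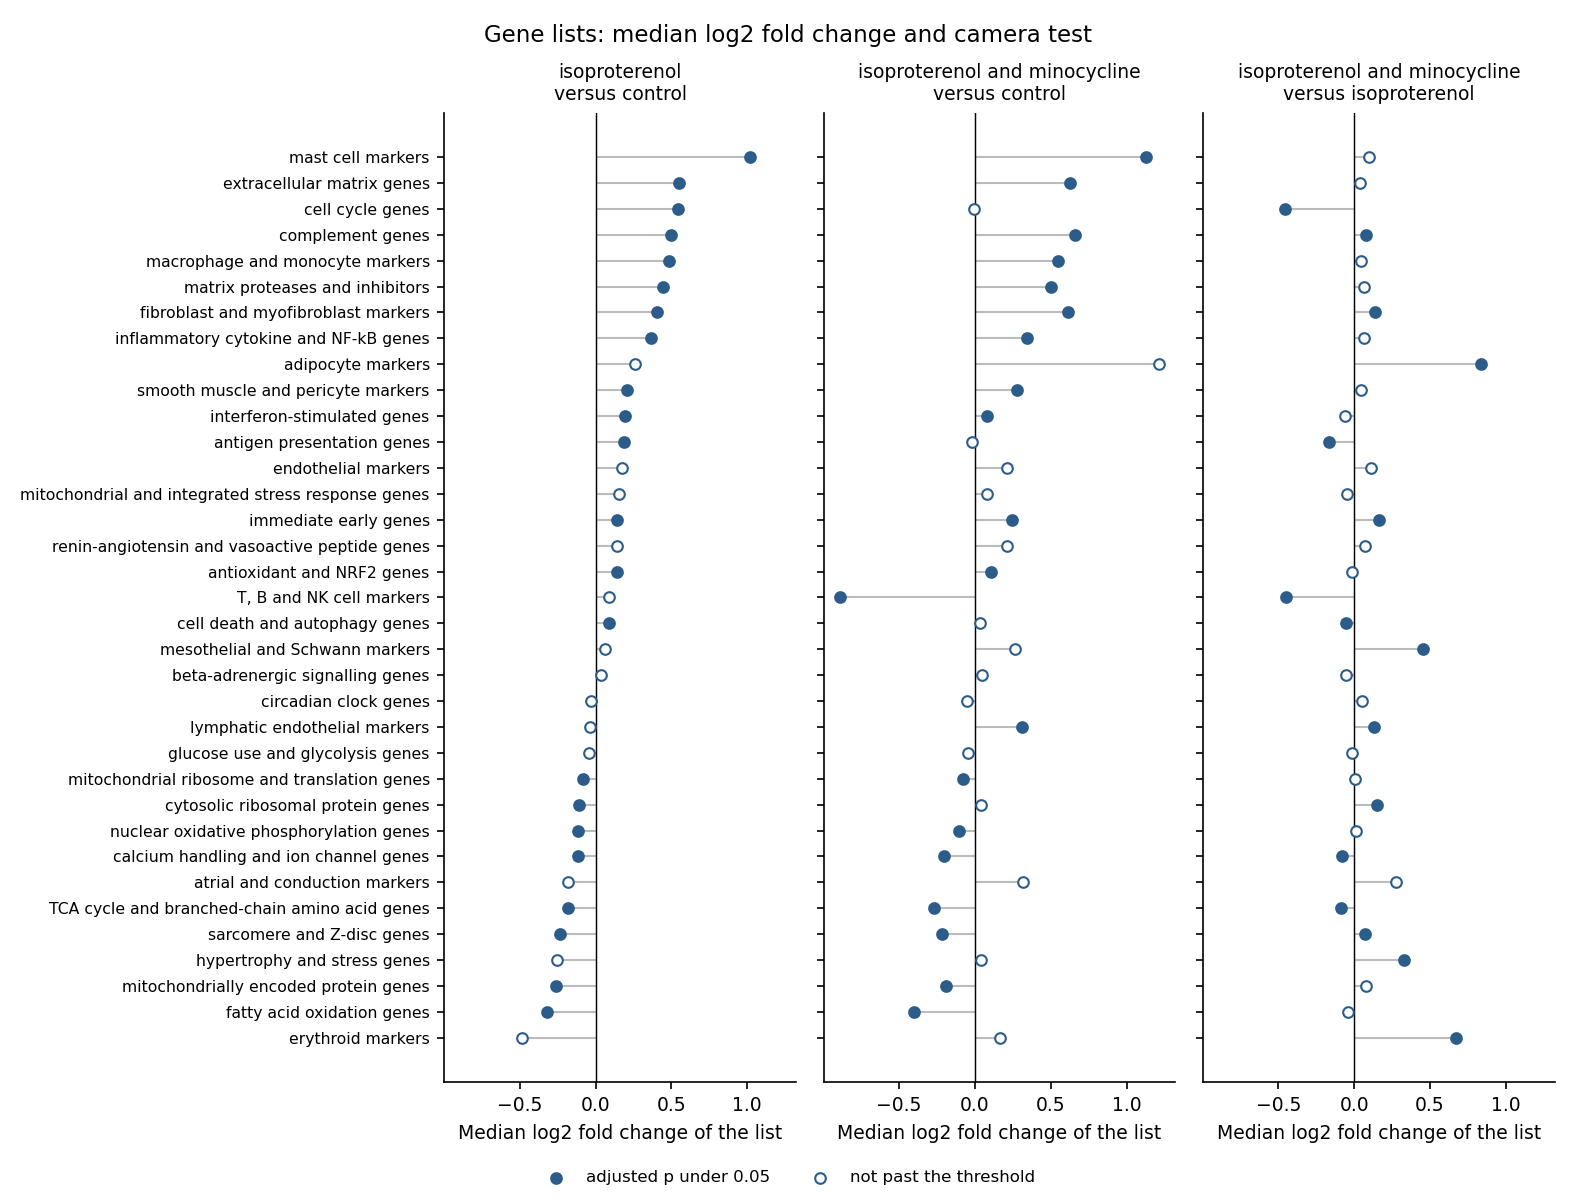
Median log2 fold change (horizontal axis) of each of the 35 tested gene lists (vertical axis) in the 3 comparisons, 1 panel each, with filled points for lists called by camera and open points for the others. Camera called 22 lists for isoproterenol versus control, 20 for isoproterenol and minocycline versus control and 16 between the isoproterenol groups.

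The response to isoproterenol without and with minocycline was then compared gene by gene. Of the 922 genes that rose with isoproterenol alone, 707 (76.7%) also rose in hearts given both drugs, among them Timp1, Tnc, Lgals3 and C3, and of the 747 that fell, 555 (74.3%) also fell, among them Hadh, Fabp3, Myom2 and Acta1. Both comparisons use the same control libraries. Independent lists of these sizes would share 94.1 and 67.6 genes, and unchanged groups simulated against the same controls shared a mean of 0 genes in 20 simulations, a value that follows from their mean of 0.075 called genes per comparison. With the controls split into separate sets of 3, the median overlap over 20 splits was 171 and 163 genes, against 15.2 and 10.7 for independent lists. Among 13281 genes, which are not independent replicates, the fold changes correlated with r = 0.839 (simulated 0.497, split controls 0.659) and had a covariance of 0.0945 (simulated 0.0140, difference 0.0805). They had the same sign in 81.1% of genes (simulated 66.6%, split controls 72.4%).

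To compare the size of the responses, genes were chosen in one part of the isoproterenol and control libraries and measured in the other part over 40 such divisions. The chosen genes moved by 0.671 ± 0.127 with isoproterenol alone and by 0.706 ± 0.0980 on the log2 scale with added minocycline (SD over divisions), a median ratio of 1.03 that ranged from 0.972 to 1.47. No p-value was computed for this ratio, since the divisions reuse the same libraries. Leaving out each minocycline library in turn, a check added after the data were seen, gave median ratios of 1.001 to 1.071. Of the 7 genes called with added minocycline, 4 had been called in the opposite direction in isoproterenol versus control, and the same isoproterenol libraries enter both calls. Ptgds stood at 339, 165 and 427 CPM in control, isoproterenol and both drugs, and 2210407C18Rik at 2.42, 6.86 and 2.703 CPM. Their calls in isoproterenol versus control (adjusted p = 1.01e-04 and 1.34e-04) were kept without each single library. Prnd stood at 2.17, 4.49 and 1.09 CPM and H2-Ab1, which rose with isoproterenol in 4 of 6 libraries, at 20.9, 27.1 and 16.5 CPM. Their calls in isoproterenol versus control (adjusted p = 0.0451 and 0.0429) were lost without Isoproterenol 3, 4, 5 or 6 or Control 3, 4, 5 or 6. The call of Prnd was also lost without Control 1, Isoproterenol 1 or 2 or Isoproterenol and minocycline 3, and that of H2-Ab1 without Control 2 (adjusted p up to 0.102 and 0.0950 without 1 library). Both were also lost with no filter on low counts and without the 4 libraries high in Myl7 (adjusted p = 0.00388 to 0.176 and 0.0302 to 0.256 over the alternatives). Of the other 3, H2-Aa and Camk2b were not called in isoproterenol versus control (H2-Aa was without Isoproterenol 1, adjusted p = 0.0215), and 3425401B19Rik fell there too.

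**Figure D5:**
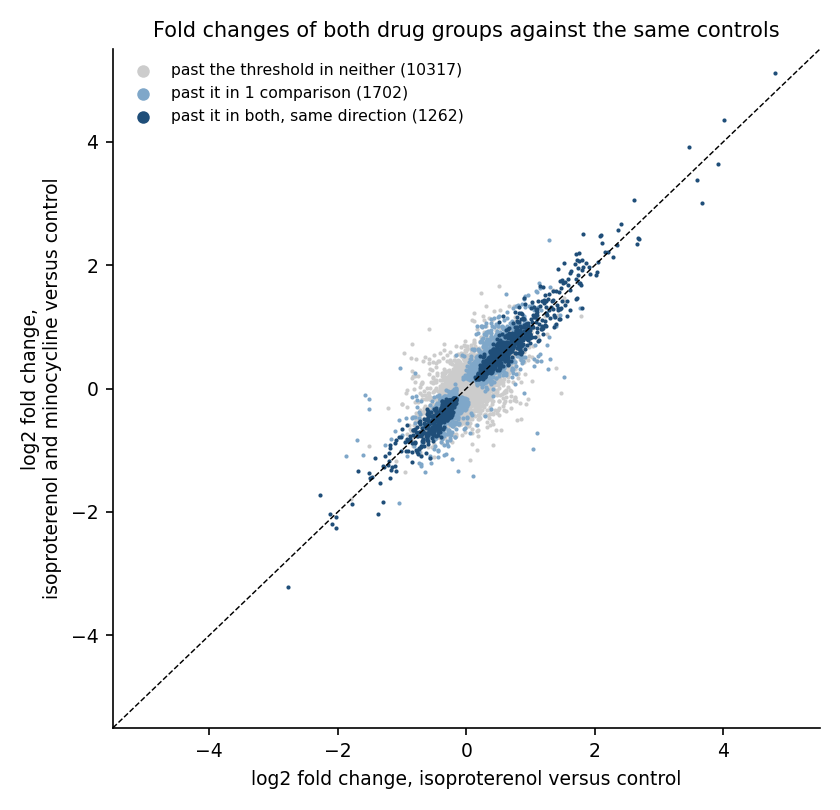
Log2 fold change of each tested gene with isoproterenol versus control (horizontal axis) against isoproterenol and minocycline versus control (vertical axis), with genes called in 1 or both comparisons coloured. The 707 genes higher and the 555 genes lower in both lie along the diagonal, and r over all 13281 genes was 0.839.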

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

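The tests on Myl7, Cd74, Lyz2, Fscn1, Zbtb46, Igkc, Ighd, Ccr2, Ly6c2, Ptprc and Lyve1 were chosen only after the values of these genes were seen. In 498 groups of 6 libraries, for the 129 genes that the text names, 35 lists, the total count and the mitochondrial share, the highest or lowest library was set against the others by Dixon's test. In 32 groups the gap to the nearest other library exceeded 0.625 of the range. Chance gives about 1 in 20, or 24.9 groups, and no cause was tested for any of these values.

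Control 1 had 175 CPM of Gnai2 (141 to 151 in the others) and 27.1 CPM of Nr4a3 (3.53 to 10.7 in the others). Control 2 had 135 CPM of 3425401B19Rik (101 to 113 in the others), 1228 CPM of Acta1 (245 to 607 in the others) and 6868 CPM of Atp2a2 (8137 to 8592 in the others). It also had 108 CPM of Postn (36.3 to 55.8 in the others). Control 3 had 137 CPM of Col3a1 (82.6 to 100.3 in the others) and 28.8 CPM of Serpina3n (9.90 to 14.4 in the others). Control 6 had 13.5 CPM of Fos (4.51 to 7.14 in the others), 52699.5 CPM of mt-Co2 (59805 to 62029 in the others) and 43.0% of counts from mitochondrially encoded genes (45.1 to 46.2%). Isoproterenol 1 had 7.42 CPM of Adrb1 (4.04 to 4.88 in the others), 189 CPM of Fhl1 (165 to 168 in the others) and 9.38 CPM of Mpeg1 (11.4 to 12.6 in the others). Isoproterenol 3 had 299.9 CPM of Col3a1 (170.2 to 219 in the others), 3.28 CPM of Cyp1a1 (0.193 to 1.27 in the others) and 9.005 CPM of Tnc (4.67 to 5.76 in the others). Isoproterenol 4 had 86.0 CPM of Nr4a3 (15.3 to 33.1 in the others). Isoproterenol 5 had 368 CPM of Gpx3 (245 to 289 in the others), 96.3 CPM of Myl7 (8.44 to 40 in the others) and a mean log2-CPM of 6.75 over the fatty acid oxidation genes (6.89 to 6.97). Isoproterenol and minocycline 2 had 1.14 CPM of Cyp1a1 (0.246 to 0.568 in the others), 5481 CPM of Myl2 (6372 to 6767 in the others) and 206 CPM of Myl7 (10.3 to 69.6 in the others). It also had 4.12 CPM of Ramp1 (1.53 to 2.39 in the others). Isoproterenol and minocycline 4 had 3.37 CPM of Clec4d (1.78 to 2.18 in the others), 5.71 CPM of Ms4a7 (2.59 to 3.73 in the others) and 612 CPM of Myoz2 (474 to 516 in the others). It also had a mean log2-CPM of 5.92 over the antioxidant and NRF2 genes (5.75 to 5.80). Isoproterenol and minocycline 5 had 4.78 CPM of Camk2b (5.56 to 6.00 in the others) and 38.4 CPM of Rps28 (45.4 to 48.8 in the others). Isoproterenol and minocycline 6 had 2.94 CPM of Prnd (0.403 to 1.13 in the others).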

How the results depend on the processing

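The tests without the 4 libraries above 80 CPM of Myl7, those with the atrial marker mean as a covariate and the response ratio without single libraries were chosen only after the data were seen. No called gene that the naming rule picks changed sign under any setting. Of these genes, not all of which the text names, 98 of 129 for isoproterenol versus control, 1 of 7 for added minocycline and 111 of 138 for both drugs versus control kept their call in each of 10 settings, and 113, 1 and 121 kept it without each single library. Rises and falls stayed within 1.5 times the reported counts under RLE and upper-quartile scaling, without and with a stricter filter, with limma-voom and without mitochondrially encoded genes. The cause of the other differences was not tested, except where a threshold or fewer libraries make them by construction.

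For isoproterenol versus control there were 400 rises and 144 falls of at least 1.5-fold, 372 and 309 without the 4 libraries high in Myl7, and 1166 and 895 with the atrial covariate. With single libraries left out, rises ranged from 580 (without Control 4) to 1020 and falls from 499 (without Control 4) to 857. For both drugs versus control the counts were 609 and 229 at 1.5-fold, 756 and 613 without the 4 libraries and 1369 and 1225 with the atrial covariate, with 957 to 1501 rises and 832 to 1429 falls as single libraries were left out. For added minocycline, DESeq2 gave 14 rises and 21 falls. A fit of the 12 libraries gave 1 fall, the atrial covariate 2 rises, and the fit without the 4 libraries 0 falls in edgeR (450 at an unadjusted p under 0.05). Without single libraries it gave 1 to 2 rises and 0 to 11 falls. The lowest came without Isoproterenol 6 or Isoproterenol and minocycline 1 or 4, the highest without Isoproterenol and minocycline 6.

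Of 22, 16 and 20 lists called for isoproterenol versus control, added minocycline and both drugs versus control, camera with an estimated correlation called 1, 0 and 0 (8, 6 and 7 at an unadjusted p under 0.05). By fry 4 lists were called for added minocycline, and by exact permutation of list means 2, all among the 16. With the atrial covariate 16 were called, 12 of them among the 16, so the calls of the fibroblast, complement, immediate early and TCA cycle lists ended (adjusted p = 0.442, 0.442, 0.0529 and 0.146). Called in their place were the interferon-stimulated, mitochondrially encoded, nuclear oxidative phosphorylation and mitochondrial ribosome lists (adjusted p = 0.0395, 0.0290, 4.45e-04 and 0.0234). In the other comparisons fry called 20 and 19 (18 and 16 of them camera's) and the permutation test 20 and 18 (18 and 16). The ratio of the responses was 1.03, and 1.05 with a looser choice of genes, 1.035 for genes of at least 1 CPM and 1.001 to 1.071 without single libraries.

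Other divisions of the 12 libraries of a comparison tested whether the calls go beyond chance, with 100 of 462 divisions each. For isoproterenol versus control 1 of 100, the real one, gave as many as 1669 called genes and the highest other gave 27. For both drugs versus control 1 of 100 gave as many as 2557, and the highest other, which moved 1 library of each group, gave 1604. Chance is argued against for both, although 1 of 100 is the smallest share that these divisions allow. For added minocycline 3 of 100 gave at least the 7 genes of the real one, a share under 0.05, but the highest other called 1371. That points to a structure among these libraries that is not the treatment. In simulated counts with the depth, number and spread of these libraries, 20 to 36% of 1.25-fold and 84 to 92% of 2-fold changes were recovered. Which of depth, number and spread limits the calls was not tested. Each simulation changed 50 genes per fold size at once, and the adjustment is stricter where fewer genes change. With 7 genes called for added minocycline, these shares may therefore overstate what that comparison could recover.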

Other observations

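The tests of relations between lists, of the cell types behind MHC class II genes and of the tissue behind Ptgds, and the genes Ly6c2, Ccr2, Ptprc and Lyve1, were chosen only after the results were seen. Across the 12 libraries given isoproterenol, with or without minocycline, the matrix list ran against the TCA cycle and branched-chain amino acid list and with macrophage markers. The mean log2-CPM of the extracellular matrix list and that of the TCA cycle and branched-chain amino acid list had r = -0.855 (permutation p = 0.00019, adjusted p = 9.00e-04) and rho = -0.769 (permutation p = 0.00489, adjusted p = 0.0147) over 6 such relations computed. The adjustment over these relations does not cover the choice of these lists among the 35 tested. Without the 2 libraries farthest in matrix expression r was -0.734. Matrix and macrophage means had r = 0.891 (permutation p = 3.00e-04, adjusted p = 9.00e-04) and rho = 0.818 (permutation p = 0.00190, adjusted p = 0.0114), and r = 0.853 without those 2 libraries.

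Within the groups the same signs were found with less certainty. In the 6 libraries given both drugs, matrix against TCA means gave r = -0.945 (exact permutation p = 0.00833, adjusted p = 0.0167; rho = -0.771, exact p = 0.103, adjusted p = 0.154), and matrix against macrophage means r = 0.952 (exact permutation p = 0.0472, adjusted p = 0.0708; rho = 0.771, exact p = 0.103, adjusted p = 0.154). Without the 2 farthest libraries they were -0.832 and 0.953. In the 6 isoproterenol libraries r was -0.676 and 0.716 (exact permutation p = 0.161 and 0.117, adjusted p = 0.161 and 0.140; rho = -0.714 and 0.657, exact p = 0.136 and 0.175, adjusted p = 0.163 and 0.175). There r was -0.0388 and -0.0319 without the 2 farthest libraries, so in that group the relations rest on those libraries. Matrix and macrophage markers come from cells other than myocytes, and whether the mix of cells or their expression differed between libraries was not tested.

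MHC class II genes had a median log2 fold change of -0.58 with added minocycline, and 7 of 7 were lower, such as Cd74, the invariant chain, at 83.5 CPM in isoproterenol and 55.8 CPM in libraries given both drugs (the same isoproterenol libraries enter the median of 0.30 for isoproterenol versus control). Fewer macrophages as a whole as the cause is argued against. Of 36 macrophage and monocyte markers 31 were tested. Their median was 0.045 (SE 0.045), above the -0.29 that this cause would need at most, with Lyz2, an abundant one, at 145.5 and 157 CPM. The SE of each marker median here comes from a bootstrap over markers and does not measure the spread between libraries. A smaller subset derived from monocytes stays open and was not tested. Of the 31 markers 12 were lower, among them Ly6c2, Ccr2 and Ptprc (log2 fold changes -0.71, -0.46 and -0.41, SE 0.30, 0.20 and 0.13, in 5, 6 and 6 of 6 libraries). The other 19 were higher, among them Lyve1 (0.56, SE 0.17, 6 of 6 libraries). None of these 4 passed the threshold (edgeR's adjusted p = 0.593, 0.607, 0.455 and 0.455). Ptprc marks leukocytes in general, and Lyve1 is also in the lymphatic endothelial list, which camera called higher here. Neither therefore tells monocyte-derived from resident macrophages. Fewer dendritic cells stay open, since 6 of 16 markers were tested, with a median of -0.14 (SE 0.13), and Fscn1 at 19.3 and 13.99 CPM but Zbtb46 at 12.2 and 12.4, and so do fewer B cells, since only Ighm, Igkc and Ighd of 12 markers were tested, with a median of -0.98 (SE 0.39) at low levels (Ighm 3.26 and 2.38 CPM). A hypothesis for a follow-up is that minocycline may lower MHC class II expression per cell, which staining of sorted cells would test and these data cannot.

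Ribosomal protein genes had a median log2 fold change of 0.15 with added minocycline, and 64 of 64 were higher. Genes were matched by level and by the length and GC content of the longest annotated transcript of each gene. A bias by these measures is argued against as the whole cause. The medians of 1000 lists of matched genes had an upper bound of 0.041, below the 0.075 that is 0.5 times the observed median. The longest transcript need not be the one expressed, so a bias by the length or GC content of expressed transcripts stays open. The large mitochondrial share of the counts is argued against too, with a median of 0.16 when mitochondrially encoded genes are left out. Its SE of 0.0069 comes from a bootstrap over the genes and does not measure the spread between libraries. A single library as the cause is also argued against, since the lowest median without 1 library was 0.14, without Isoproterenol 6. List means per library overlapped between the groups (6.95 to 7.17 and 7.07 to 7.27), and the same isoproterenol libraries enter the lower values of isoproterenol versus control. That minocycline may raise ribosomal protein transcripts is a hypothesis only, as no group given minocycline alone was analysed here.

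Ptgds was at 339 ± 66.4 CPM in control, 165 ± 26.2 in isoproterenol and 427 ± 81.4 CPM in libraries given both drugs. Atrial, fat or epicardial tissue taken with the ventricle is argued against as the whole cause: with the atrial, adipocyte and mesothelial marker means of each library as covariates, the log2 fold change for added minocycline was 1.35 (SE 0.18, edgeR's adjusted p = 0.0279), against 1.37 (SE 0.14) without them. For isoproterenol versus control it was -1.08 (SE 0.19, edgeR's adjusted p = 0.00335) with them and -1.04 (SE 0.14) without, and the same isoproterenol libraries enter both. A response of this gene to minocycline remains a hypothesis, which a group given minocycline alone would test.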
